A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

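The series follows Bacillus subtilis strain 168 grown in batch fermentors at 37 °C and pH 6.4 in defined medium. One culture received 3 mM potassium sorbate and a control culture did not, and RNA of both was compared before the addition (0 min) and every 10 min up to 50 min. On every array the control RNA carried Cy3 and the RNA of the sorbate culture carried Cy5, per the labels, so dyes were not swapped. There were 12 arrays, 2 for each of the 6 time points, which were taken as the arrays of the 2 independent experiments that the series design states. The headers do not tell which array belongs to which experiment.

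The scanner files hold spot intensity and local background intensity of each channel, written by image software without normalization, per the file headers. Each file has 9216 spots given by position, with every probe spotted as a pair, and no gene names. The series table holds log2 ratios that the authors deposited, 1 combined value for each gene and time point, for 3909 gene symbols. How the authors normalized and combined them is not stated in the labels. The table has no error, number of arrays or p for any gene.

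Intensities were corrected with normexp (offset 50) and log2 ratios of Cy5 over Cy3 were normalized within each array by loess (span 0.3) in limma 3.58.1 on R 4.3.3. Spot pairs were averaged. A set of 83 spot pairs with signal in Cy3 alone, found as log2 ratios under -1 on both 0 min arrays, was given weight 0 in the loess and then left out; this rule was set after the 0 min arrays had been seen. The remaining 4525 probes were fitted with lmFit and eBayes with all 12 arrays sharing 1 estimate of the spread. Arrays of different time points were treated as independent, although the samples of a time course were withdrawn repeatedly from the same cultures. Each time point, and the mean of 10 to 50 min, was compared with 0 min, which removes a dye bias or a difference between the cultures that was there before. The mean of 40 and 50 min was compared with the mean of 10 and 20 min, and the 0 min ratio was tested against 0. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called.

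The test was run on simulated data, with 20 runs on 4525 probes in which every array drew its own replicate residual with its own sign. This form replaced an earlier one that gave paired arrays opposite residuals. Of 200 changed probes, the mean comparison recovered 78.2% at log2 0.5, 96.4% at 1, 99.9% at 2 and 100% at 4, and 6.05% of its calls were false. The comparison of 40 and 50 min with 10 and 20 min recovered 81.6%, 98.2%, 99.7% and 99.9% at these sizes, with 6.83% of calls false. With no change simulated, the first made 0.6 calls on average and at most 4, and the second 0.25 and at most 1. The simulated false share thus lay above 5%, the level set by the adjustment. Simulated arrays were independent, whereas residuals of the real arrays correlated between time points with r of -0.0778 to 0.460. The simulated shares therefore need not hold for the real arrays.

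The probes carry no names and the named genes carry no replicates, so the gene level has no test. This departs from the plan fixed before the data were examined, which named genes by adjusted p. A gene was instead taken as higher or lower where its log2 ratio minus its 0 min value was at least 1 (2-fold). This rule was chosen after seeing the data. Before it, 4 forms of a test against the differences between replicate arrays had been run and their counts seen: 41, 1524, 3 and 21 genes for the mean of 10 to 50 min, and 33, 964, 0 and 0 for late against early. Their spread follows the background correction and the probes chosen, and the table holds no intensity to choose between them, so none was used for calls. The counts of 41, 3 and 21, and of 33, 0 and 0, are those with plain background subtraction, the correction used in the scale check below. The share of probes past the test at each size was then looked at, and the 2-fold line taken. At that line limma called 98.6% of 141 probes in the mean comparison, 98.5% of 67 in late against early and 95.5% of 134 at 50 min, the lowest of the time points after 0 min, but 7.69% of 13 at 0 min. With plain background subtraction it called 73.5% of 310, 59.1% of 149, 61.5% of 338 and 56.5% of 301. The scale of the table was compared with plainly subtracted values alone, so the higher shares are not shown to hold for its genes. At 0 min, 6 of 3909 genes lie beyond the 2-fold line.

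Scale and direction of the table were checked against the scanner values after plain background subtraction and loess; normexp values were not compared. Genes were linked to their nearest probe on 5 of the 6 time points (distance ratio under 0.4) and the time point left out was compared. The correlation across genes was 0.993 to 0.998 for 10 to 50 min and 0.838 at 0 min, with slopes of 0.862 to 1.00, and 553 to 821 genes were linked against 27 to 49 with the sign turned. The genes linked with the sign turned also correlated with r of 0.899 to 0.987 for 10 to 50 min, but 0.0704 at 0 min. Direction thus rests mainly on the number of links, and genes without a link were not checked. These links were not used to name probes. Column medians of the table lay between -0.01 and 0.01. Of its symbols, 2891 are in the ASM904v1 annotation, which was used only for names and gene order.

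The genes named were the 10 furthest above and the 10 furthest below 0 min in the mean of 10 to 50 min with all 5 time points on the same side, the 3 furthest each way at each time point, the 5 furthest each way between late and early, up to 4 members of each list with the largest absolute change, and the 3 largest ratios each way at 0 min. The sizes of these groups were fixed before the data were examined; size replaced p as the criterion, and 5 time points replaced 10 arrays. The 40 gene lists were fixed then too. Each list was described by the percentile of its median among 10000 random lists of its size, which were not matched on expression because the table holds none. Lists outside percentiles 0.5 to 99.5 are reported as standing apart; that line was chosen after cameraPR results had been seen. It describes these values and is not a test.

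Alternatives for the probe counts were no background correction, plain subtraction, offset 0, median centring, scale and Aquantile normalization, leaving out the 25% dimmest probes, eBayes with trend and robust, the ratio against 0, and leaving out each array. Added after seeing the data were the array series as a block and as a random block, keeping the green-only spots, size lines of 0.5 and 1.5, leaving out a time point of the table, the ratio against 0 for its genes, late against early from 20 and 40 min or 10 and 50 min alone, preset correlations of 0.05 and 0.1 in cameraPR, and the 4 forms named above. Lists were not run under other normalizations, with an estimated correlation or with fry, since the table has no replicates, and no count adjusted over a list alone was made. Figures were drawn with matplotlib 3.10.9.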

Results

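The data are 12 arrays comparing a culture of Bacillus subtilis given 3 mM potassium sorbate, a weak-acid food preservative, with a control culture, 2 arrays at 0 min and at every 10 min up to 50 min. Signals stood clear of background for most spots: between 57.0% and 81.1% of spots exceeded 2 times their background in both channels, and the Cy3 signals of paired spots correlated with r of 0.977 to 0.997 across spots. The lowest value of both measures was that of replicate 1 of 0 min, which enters every comparison with 0 min. Log2 ratios of the 2 arrays of a time point correlated with r of 0.33 across probes at 0 min, where little difference was present, and 0.85 to 0.93 later. The number of arrays limits the precision. Values of named genes come from the authors' table, which has 1 combined value per time point, so they carry no error and no gene is said to have passed a test.

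The first comparison asks which transcripts differed over the whole time with sorbate, as the mean of 10 to 50 min against 0 min. The genes furthest above their 0 min value were yhcB (log2 4.54), yhbJ (3.66), yhbI (3.64) and yhcA (3.42), 4 neighbours on the chromosome, followed by yxkJ (3.18), yveF (2.99), yveG (2.89), ureB (2.84), a urease subunit, fabHB (2.84), which starts fatty acid chains, and yuiA (2.83). yhcB had a 0 min ratio of -1.45, and without subtracting it its mean was 3.10, below those of yhbI, yhbJ and yhcA. The genes furthest below were ycsI (-2.58), ycsG (-2.58), kipI (-2.48), ycsK (-2.39), ycsF (-2.26) and kipA (-2.22), genes of the kip region, and then ykrT (-1.98), lysC (-1.93), an aspartokinase, lip (-1.91), a lipase, and metE (-1.66), methionine synthase. In all, 102 genes were at least 2-fold higher and 78 at least 2-fold lower, and 174 of these 180 lay on the same side of 0 min at all 5 time points.

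**Figure D1:**
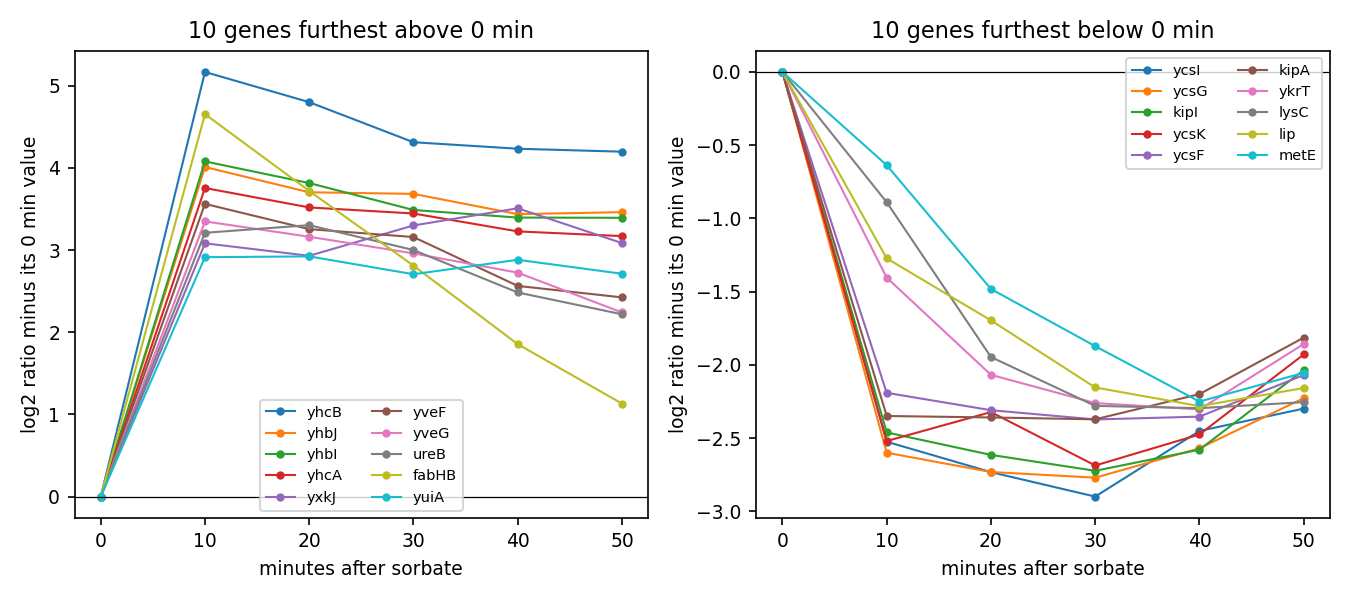
Log2 ratio of sorbate over control minus the 0 min value (vertical axis) against minutes after sorbate (horizontal axis) for the 10 genes furthest above and the 10 furthest below 0 min, 1 combined value per point. yhbJ lies at 4.01 at 10 min and 3.46 at 50 min, while fabHB goes from 4.66 at 10 min to 1.13 at 50 min and metE from -0.64 to -2.05.

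Lists with higher values were led by the bkd operon for degradation of branched-chain keto acids, with a median of 1.41 and 7 of 8 measured genes at least 2-fold higher (bkdR 1.62, lpdV 1.54, bcd 1.44). The FapR regulon of fatty acid and phospholipid synthesis had a median of 1.07, with all 8 measured members above 0 min and 4 at least 2-fold higher (fabHB 2.84, fabI 1.60, fabG 1.36). Without subtracting 0 min the median of this list was 0.75 and fabHB was at 2.41. Citric acid cycle genes had a median of 0.73 and all 12 were above 0 min (citZ 1.25, sdhB 1.13, citB 1.12). Genes of the CodY regulon apart from ilv-leu had a median of 0.61 (0.45 without subtracting 0 min), with 33 of 47 above 0 min and 14 below. At least 2-fold higher were 12, among them ureB, ureA (2.71), ureC (2.28) and dppE (1.51) of dipeptide uptake. The ilv-leu genes, also under CodY, had a median of 0.22 and did not stand apart from random lists (percentile 91.37). Genes of sugar and carbon use repressed by CcpA had a median of 0.41 (0.24 without subtracting 0 min), led by gntR (1.88), glpF (1.74) and mtlA (1.62), whose 0 min ratios were -0.98, -0.67 and -0.95.

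Lists with lower values included arginine synthesis, with a median of -0.996 and all 10 measured genes below 0 min (argD -1.18, argH -1.07). This value rests on 20 and 30 min, where the medians were -3.09 and -1.64, and was -0.86 without subtracting 0 min, against -0.98 for purine synthesis. Purine synthesis had a median of -0.92 with all 18 genes below (purN -1.34, purE -1.26), histidine synthesis -0.83 with all 8 below (hisB -0.91), ATP synthase -0.54 with all 9 below (atpE -0.68) and pyrimidine synthesis -0.53 with all 10 below (pyrD -0.64). The SigM and SigX regulons of the cell envelope had a median of -0.51, and their lowest members were dltB (-1.46), dltC (-1.41), dltD (-1.40) and dltA (-1.28), which add D-alanine to teichoic acids. Methionine and cysteine synthesis had a median of -0.35 with 9 of 28 genes at least 2-fold lower (ykrT -1.98, metE -1.66, ykrW -1.58). Smaller shifts were a median of -0.29 for the SigW regulon, -0.24 for motility and chemotaxis (-0.13 without subtracting 0 min), -0.21 for the SigB general stress regulon and -0.20 for ribosomal proteins. In the SigB list ydaB (1.68) and yvyD (1.36) were higher while 37 of 49 genes were below 0 min.

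Of 40 lists, 8 lay above and 11 below the middle 99% of random lists, where 0.4 would be outside by chance if genes were independent, which genes of an operon are not. Without subtracting 0 min 20 lists lay outside: motility and thiol stress no longer did, while multidrug efflux, competence and the list of surfactin, antibiotics and biofilm matrix did. In cameraPR at a preset correlation of 0.01, 5 of the 19 did not pass: ribosomal proteins (adjusted p = 0.0559), the SigB regulon (adjusted p = 0.0979), tryptophan and aromatic amino acid synthesis (median 0.46, adjusted p = 0.0762), thiol stress (0.41, adjusted p = 0.180) and glycolysis (0.32, adjusted p = 0.180). At 0.05 motility was also lost (adjusted p = 0.159), and at 0.1, where 10 lists passed, also pyrimidine synthesis and the CcpA list (adjusted p = 0.0541 for both), ATP synthase (adjusted p = 0.0587) and the SigW regulon (adjusted p = 0.164). Of the 16 lists that passed at 0.01, 2 were not among the 19: phenolic acid decarboxylases (adjusted p = 2.50e-08, and 1.34e-06 at 0.05) and multidrug efflux (median -0.27, adjusted p = 0.00478, 0.0330 at 0.05 and 0.102 at 0.1). cameraPR compares genes of 1 combined table and is no test across arrays. The 21 lists not standing apart had medians between -0.27 and 0.27. Among them the phenolic acid decarboxylase list had a median of 0.13 and a mean of 1.19, since yveF, yveG and padC (2.52) stood far above its other members. Median and mean differed in sign for nitrogen limitation (0.06 and -0.04), early sporulation (-0.00306 and 0.06) and the SOS response (-0.07 and 0.05).

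**Figure D2:**
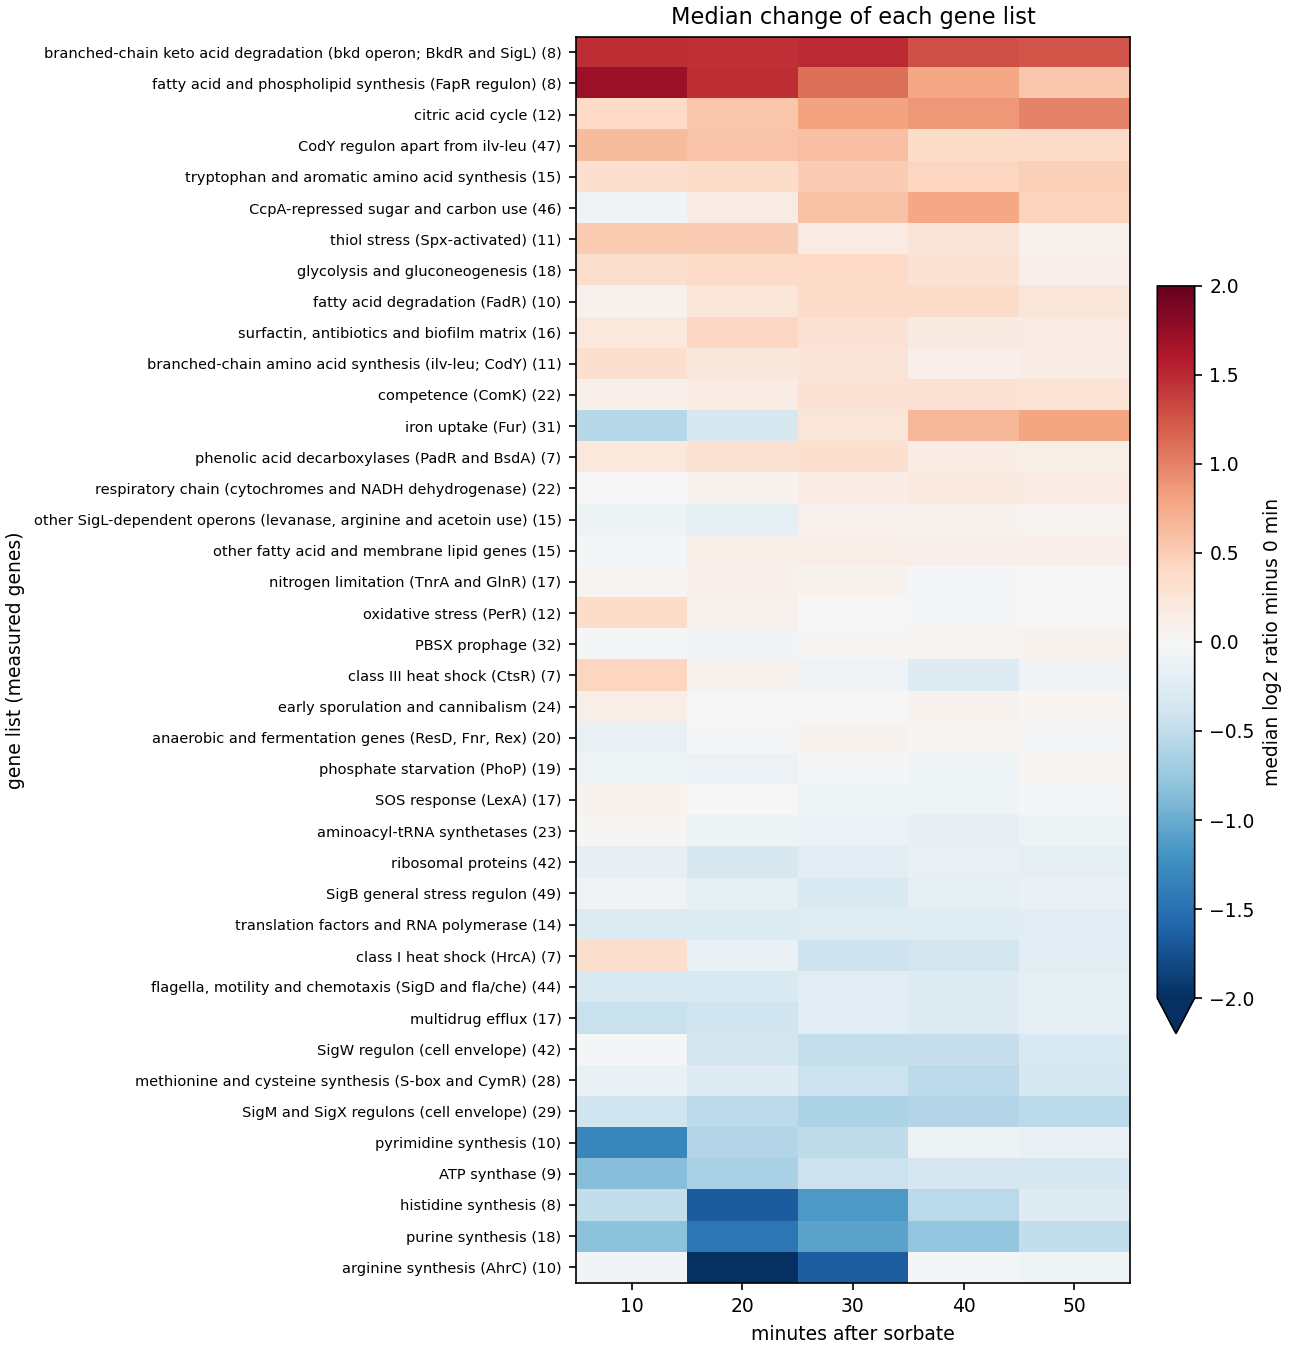
Median log2 ratio minus 0 min (colour) of each of the 40 gene lists (rows, measured genes in brackets) at 10, 20, 30, 40 and 50 min (columns); colours end at 2 either way. The bkd row lies between 1.25 and 1.49 throughout, and the arginine row reaches -3.09 at 20 min.

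With limma on the unnamed probes, 808 rose and 761 fell of 4525 in this comparison (adjusted p under 0.05), with 2013 at an unadjusted p under 0.05. Among called probes with all 10 arrays on the same side of 0 min, the largest rise was 3.51 ± 0.08 (SE; adjusted p = 3.38e-08 in limma; 10 arrays against 2) and the largest fall was -2.19 ± 0.13 (SE; adjusted p = 5.19e-06 in limma). The 10 later arrays sample the cultures of 2 experiments repeatedly. The SE and p treat these arrays as independent, so they do not rest on 10 separate cultures. Of the 1569 called probes 1399 had all 10 arrays on the same side of the 0 min mean. This held for 43.2% of all probes, against 8.90% of unchanged simulated probes that share their 0 min arrays. With arrays only centred on their median, 241 rose and 380 fell, and with the ratio set against 0 the count was 3394.

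**Figure D3:**
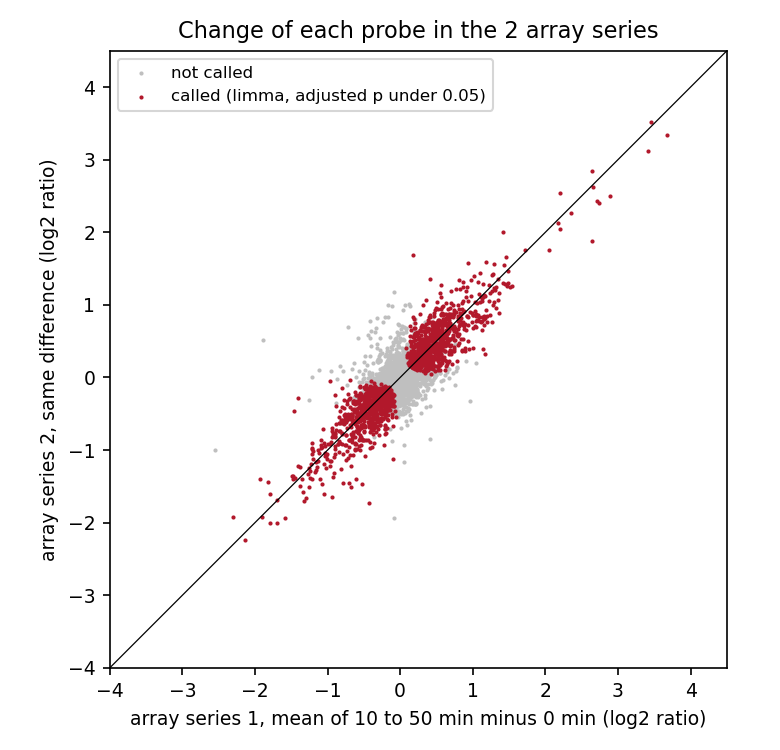
Change of each probe between the mean of 10 to 50 min and 0 min (log2 ratio) in the first array of every time point (horizontal axis) against the second array (vertical axis), with probes called by limma in red and a line of equality. The values correlate with r of 0.83 across the 4525 probes, which are not independent replicates.

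Each time point was also set against 0 min to follow the time course. At 10 min yhcB (5.17), fabHB (4.66) and yhbI (4.08) were highest and ycsG (-2.60), ycsI (-2.52) and ycsK (-2.52) lowest. At 20 min arginine synthesis genes were lowest, with argD at -3.71, carA at -3.56 and argH at -3.30; argD was at 0.14 at 10 min and -0.03 at 40 min, and argF was lowest at 30 min (-3.05). Medians of arginine synthesis went from -0.05 at 10 min to -3.09, -1.64, -0.03 and -0.09, those of histidine synthesis were lowest at 20 min (-1.67), and those of pyrimidine synthesis at 10 min (-1.31). From 30 to 50 min yhcB was at 4.31, 4.23 and 4.20, the highest values at these times. Its place as highest at every time point rests on its 0 min ratio of -1.45: without subtracting 0 min, the highest genes were fabHB (4.23) at 10 min, yhbI (3.91) at 20 min, yhbJ (3.67) at 30 min, yxkJ (3.61) at 40 min and yhbI (3.49) at 50 min. At 50 min lysC (-2.25) was among the lowest. The heat shock genes groES and groEL were at 1.16 and 1.25 at 10 min and -0.11 and -0.06 at 50 min.

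The number of genes at least 2-fold apart from 0 min was 148 higher and 96 lower at 10 min, 131 and 125 at 20 min, 132 and 118 at 30 min, 150 and 86 at 40 min, and 122 and 65 at 50 min. Of these, 54 genes were higher and 29 lower at all 5 time points, and 3 were beyond the line in both directions. All time points share their 0 min values, so these genes are not 5 independent observations. With limma, 775 probes rose and 712 fell at 10 min, 563 and 591 at 20 min, 622 and 609 at 30 min, 631 and 594 at 40 min, and 387 and 314 at 50 min. Whether these numbers differ between time points was not tested. Median centring changed them by over 1.5 times at every time point, to 365, 266, 371, 290 and 1405. Its rises and falls were 157 and 109 at 20 min and 97 and 274 at 30 min. Leaving out 1 array gave 617 at 20 min (replicate 2), 743 at 30 min (replicate 1), 799 and 764 at 40 min and 435 and 369 at 50 min (replicates 1 and 2). Scale normalization gave 907 at 10 min, below its 1388 at 20 min, and the ratio against 0 gave 2350, 2157, 2050 and 1306 at 10, 30, 40 and 50 min.

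**Figure D4:**
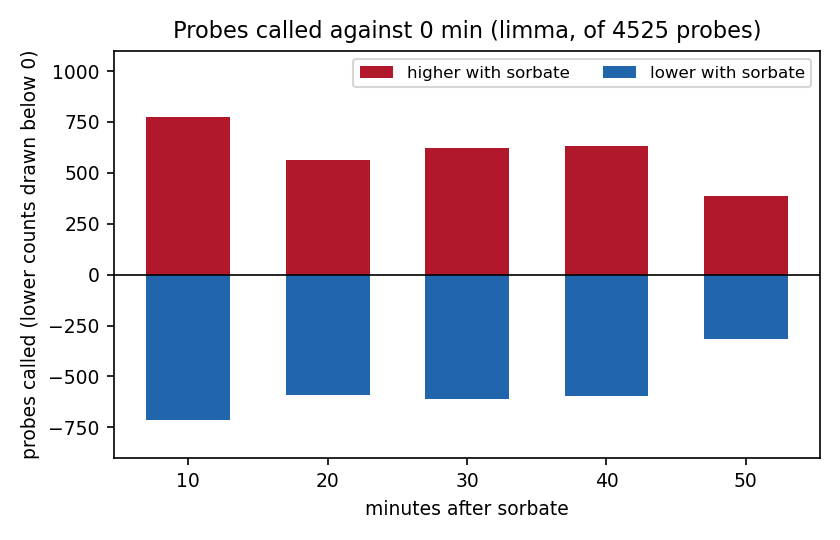
Probes called by limma at each time point against 0 min (horizontal axis, minutes), with rises drawn upward and falls downward (vertical axis, number of probes). The counts lie between 701 at 50 min and 1487 at 10 min.

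The third comparison asks how the response moved between 10 and 20 min and 40 and 50 min. Iron uptake genes under Fur were higher late: all 31 measured genes, 23 of them at least 2-fold, with a median difference of 1.22. They were led by yxeB (2.77), fhuD (2.48), dhbB (2.32), ykuP (2.21) and dhbC (2.09); yxeB and fhuD serve siderophore uptake, dhbB and dhbC siderophore synthesis, and ykuP codes for a flavodoxin. Arginine synthesis (median 1.52), pyrimidine synthesis (0.82), histidine synthesis (0.69), genes repressed by CcpA (0.46), purine synthesis (0.44), the citric acid cycle (0.43) and ATP synthase (0.41) were also higher late than early. The levanase genes levE (1.997), sacC (1.96) and levG (1.91) were higher too, in a list with a median of 0.02.

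The FapR regulon was lower late than early (median -1.09, all 8 genes lower, 5 at least 2-fold), and the genes furthest below their early values were fabHB (-2.69), yhfC (-1.42), fabHA (-1.27), fabG (-1.22) and ydiM (-1.20). Class I heat shock genes had a median difference of -0.44 (groES -1.11, groEL -0.90), class III genes -0.34, thiol stress genes -0.29, genes under PerR -0.27, the CodY list -0.25 and the SigW regulon -0.24. Competence genes had a median of 0.18. These were 9 lists above and 7 below the middle 99% of random lists. Competence did not pass cameraPR at a preset correlation of 0.01 (adjusted p = 0.256), and PerR and thiol stress did not at 0.05 (adjusted p = 0.0786 and 0.0747). At 0.1, where 12 lists passed, ATP synthase (adjusted p = 0.0539), the CodY list and the SigW regulon (adjusted p = 0.0652 for both) were lost too. Of the 19 lists that passed at 0.01, 4 were not among the 16 standing apart: other SigL-dependent operons (adjusted p = 1.07e-07, and 2.41e-05 at 0.05), phenolic acid decarboxylases (median -0.28, adjusted p = 0.00256, and 0.00923 at 0.05), methionine and cysteine synthesis (-0.14, adjusted p = 0.00773, and 0.0735 at 0.05) and the SigM and SigX regulons (-0.14, adjusted p = 0.0120, and 0.0853 at 0.05). Median and mean differed in sign for aminoacyl-tRNA synthetases (-0.02 and 0.01), anaerobic genes (-0.03 and 0.13) and nitrogen limitation (0.02 and -0.05). In all 66 genes were at least 2-fold higher late and 13 lower.

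**Figure D5:**
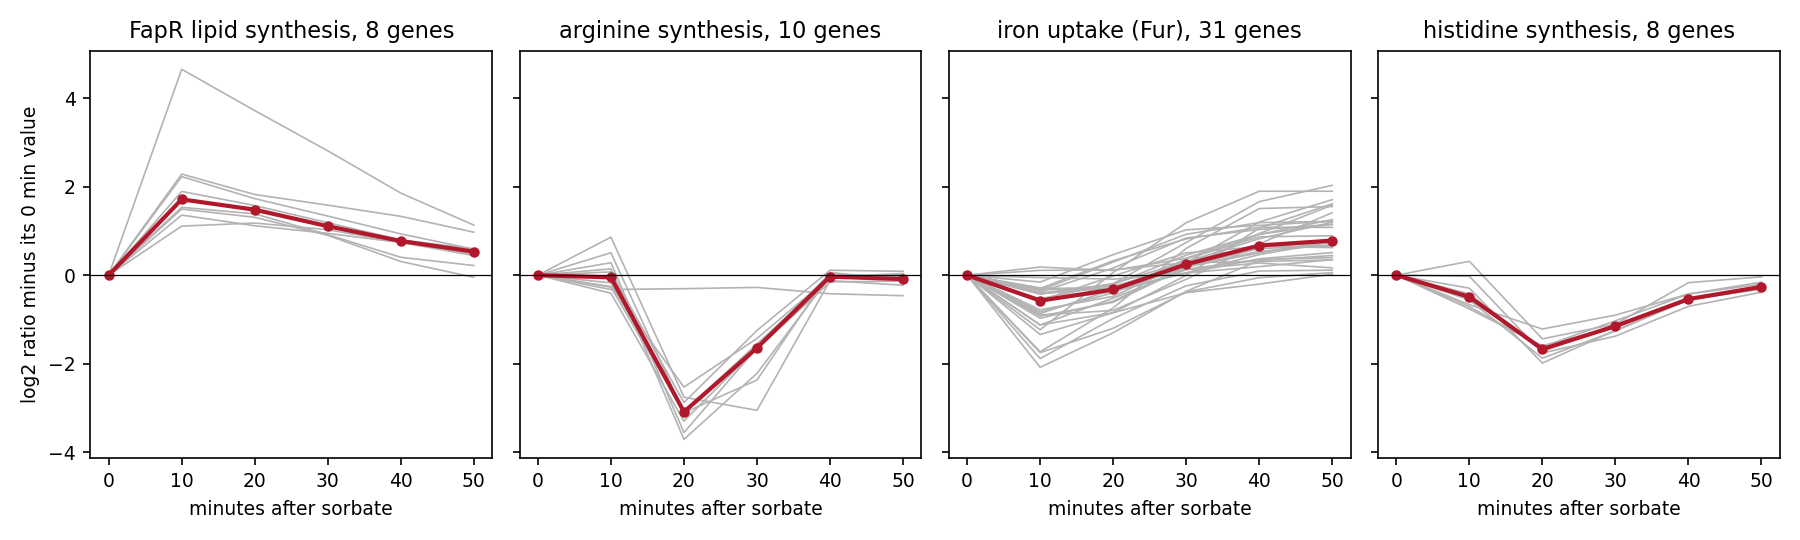
Log2 ratio minus the 0 min value (vertical axis) against minutes after sorbate (horizontal axis) for the members (grey) and median (red) of 4 gene lists. The FapR median goes from 1.71 at 10 min to 0.53 at 50 min, and the iron uptake median from -0.58 to 0.78.

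With limma, 448 probes rose and 428 fell between early and late, and 1451 had an unadjusted p under 0.05. With median centring the count was 1734, and with scale normalization between arrays it was 444.

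At 0 min, before sorbate acts, the ratio itself was compared with 0 as the background of the study. The lowest genes were yhcB (-1.45), spoIIGA (-1.14) and cwlJ (-1.08), and the highest yqaF (0.99), yosJ (0.93) and acoC (0.92). There were 6 genes at least 2-fold lower and 0 higher; limma called 8 probes, 1 above 0 and 7 below, with 710 at an unadjusted p under 0.05. This count depended on the processing: it was 814 with scale normalization, 346 above and 468 below. The log2 ratios had an SD of 0.216 and 0.188 on the 0 min arrays and of 0.379 to 0.506 on the later ones. Scale normalization gives every array the same spread, so its 0 min count does not by itself show a difference between the cultures. It was 16 and 35 without replicate 1 and 2 of 0 min, and 1 or 2 without any single array of 20 to 50 min.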

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

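The tests of yhcA and yhcB, of the iron uptake genes, and of dye bias after loess were chosen only after the results were seen; the other tests were chosen before.

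A first pattern is that 876 probes differed between 40 and 50 min and 10 and 20 min in limma. Only 1 of the 35 splits of the 8 arrays, the real one, gave as many calls in a 2-group fit, with 672 against at most 0 in any other split. This argues only against 8 arrays that do not differ by time point at all. Most other splits mix the arrays of a time point, so differences between time points enter their spread and lower their calls. Only 3 splits keep the 2 arrays of each time point together, too few for a share under 0.05, so chance among time points cannot be excluded. The late minus early change correlated with r of 0.827 across probes between the first and the second arrays of the time points, which argues against single arrays, and the Cy3 channel of the control moved more in 13.9% of called probes, which argues against a change in the control culture, though it rests on channels scaled with Aquantile. An intensity-dependent dye bias has the values it needs: with median centring only, a curve on intensity took 74.8% of the variance of this change, as the test written beforehand had required of it. Loess brought the medians of 10 groups of probes by intensity from between -0.43 and 1.12 to between -0.03 and 0.05. It takes such a curve out of each array by design, so this is no evidence. The count moved from 1734 to 876, and in the 2-group fit from 1511 to 672 in the real split and from 937 to 0 in the highest other one. The calls that remained were made with the curve taken out, which argues only against the fitted curve as the whole cause. The bound for this was set after the counts were seen and rests on splits that mostly mix time points. It cannot tell whether a dye bias that loess did not follow is among the remaining calls. Whether the trend adds to the pattern stays open.

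A second pattern is that yhcA and yhcB lay far above their 0 min values, and yhcB had a low ratio at 0 min. Without subtracting 0 min the smaller of their mean values was 3.10, so a low ratio at 0 min does not account for it. The table has no replicates, and how the authors normalized it stays open.

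A further pattern is that iron uptake genes were below 0 min at 10 and 20 min and above it at 40 and 50 min in the median, and the median of their late minus early differences was 1.22. No test across arrays was run for it; cameraPR, which sets the list against the other genes of the combined table, gave an adjusted p of 8.37e-86 at a preset correlation of 0.01 and 6.25e-46 at 0.05. Of the measured members, 100% were higher late than early, so the shift was not confined to a few of them. The members and their median had already been seen, so this describes the list and is no separate test. Some of these genes share operons and are not independent, and the authors' normalization stays open.

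The median of class III heat shock genes also lay on opposite sides of 0 min early and late, and the median of their differences was -0.34, with no test across arrays run (adjusted p = 0.00672 in cameraPR at a preset correlation of 0.01, 0.0182 at 0.05 and 0.0463 at 0.1). Single genes on opposite sides were not tested; their late minus early difference was 2.77 for yxeB, 2.32 for dhbB, 2.21 for ykuP, 2.09 for dhbC and -1.20 for ydiM. The 83 spot pairs left out as green-only had a median Cy3 signal of 5283 above background against 20.1 in Cy5, and all lie in the first of 4 block columns.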

How the results depend on the processing

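The array series as a block or random block, the controls kept, the size lines, the tests on replicate differences, the time points left out or taken alone, the ratio against 0 for genes of the table and the preset correlations of 0.05 and 0.1 were chosen after seeing the data, as were the 2-fold line and the percentile line under the reported counts of genes and lists. The other alternatives were fixed before. Where a count moved, the cause was not tested. Of the counts across all comparisons, 172 of the alternative values lay within 1.5 times the reported one and 82 did not. The 172 include Aquantile, which leaves the ratios unchanged. They also include counts with an array left out that the comparison does not use, which can move only through the shared spread. Their number is thus no measure of stability. With median centring only, the counts for the mean, 10, 20, 30, 40 and 50 min, late against early, and 0 min were 621, 365, 266, 371, 290, 1405, 1734 and 1, with 241 rises and 380 falls in the mean (808 and 761 in the reported fit), 157 and 109 at 20 min (563 and 591) and 97 and 274 at 30 min (622 and 609). With scale normalization, which gives every array the same spread, 10 min gave 907, 30 min 844, late against early 444 and 0 min 814 (346 above and 468 below, against 1 and 7). Against 0 in place of the 0 min arrays, the mean gave 3394, 10 min 2350, 30 min 2157, 40 min 2050 and 50 min 1306. The authors' table at the 2-fold line, with no test, gave 180, 244, 256, 250, 236, 187, 79 and 6 in the same order. The 0 min count was 302 with no background correction, 316 with plain subtraction, 2 with offset 0, 2 without the dimmest probes, 79 with the array series as a block and 117 with the green-only controls kept.

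Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, the counts ranged from 1056 to 1642 for the mean, 1163 to 1525 at 10 min, 617 to 1206 at 20 min, 743 to 1282 at 30 min, 764 to 1301 at 40 min, 369 to 740 at 50 min, 585 to 915 for late against early and 1 to 35 at 0 min. The arrays that moved a count by over 1.5 times were replicate 2 of 20 min (617), replicate 1 of 30 min (743), replicates 1 and 2 of 40 min (799 and 764) and of 50 min (435 and 369), each for its own time point. For 0 min they were replicates 1 and 2 of 0 min (16 and 35) and all arrays of 20, 30, 40 and 50 min (1 or 2 calls each).

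For genes of the table, tests on replicate differences gave, with subtracted values of the brightest probes, 41 for the mean, 22, 29, 0, 25 and 0 at 10 to 50 min, 33 for late against early and 0 at 0 min. With normexp values they gave 1524, 856, 1423, 736, 1350, 693, 964 and 0. With all probes they gave 3 for the mean and 0 elsewhere, and with the dimmest of the brightest probes 21 and 0 elsewhere. A line of 0.5 gave 942 genes for the mean and 396 for late against early, and a line of 1.5 gave 49 and 25. Leaving out a time point gave 169 to 215 genes for the mean. Without subtracting 0 min it was 159. Of 40 lists, 16 passed cameraPR at a preset correlation of 0.01, 15 at 0.05 and 10 at 0.1 in the mean, where 19 stood apart by percentile, and 19, 15 and 12 passed in late against early, where 16 stood apart. No named gene tried changed its direction. For genes named in the mean, leaving out a time point could not change it. They had been chosen with every time point of 10 to 50 min on the same side of 0 min. Keeping the 0 min ratio could not change it either. The changes of these genes lay at 2.83 or above, or at -1.66 or below. The 0 min ratios of all genes ran only from -1.45 to 0.99. For late against early, the reported change is the mean of the changes from the pairs of time points taken alone. Those pairs could thus not both reverse it, and the genes had been chosen as the furthest. The unchanged directions are therefore no evidence of stability for genes named in the mean, and little for the others.

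No paired analysis was possible because the headers do not state the experiment of an array. Taking the order of the files as a block, which need not follow the experiments, gave 1624 for the mean and 916 for late against early, and only the 0 min count moved by over 1.5 times. Residuals of the first and second arrays correlated between time points with r of -0.0778 to 0.460, and the random block had a correlation of 0.0360. The stated experiment as a block was not run for the same reason, and slide or scan batches were not run because each array is on its own slide and the headers give no scan date. Aquantile leaves the ratios unchanged and no spot was flagged, so these alternatives say nothing. Between 57.0% and 81.1% of spots exceeded 2 times background in both channels, and dim probes limit the rest.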

Other observations

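The groups of neighbours and their share were looked at after seeing the data. Neighbouring genes moved together in the table. Of genes at least 2-fold apart from 0 min in the mean of 10 to 50 min whose next gene was measured, 44.2% had a next gene beyond the line in the same direction, against 4.60% of all genes beyond it either way. There were 11 runs of at least 3 such neighbours. The longest was 8 genes, yxiK, yxiJ, yxiI, yxzG, yxiH, yxiG, yxzC and yxiF, between -1.65 and -1.17. Other runs outside the lists described were gcvPA, gcvT and yqhH, of which the first ones code for the glycine cleavage system (1.11 to 1.43), and yrhG, yrhF and yrhE (1.20 to 1.502). The run of yhbI, yhbJ, yhcA, yhcB and yhcC lay between 1.19 and 4.54, and dltA to dltE between -1.46 and -1.07.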
